A study of Homo sapiens with 18 samples.

How the data were processed

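The authors deposited 4 tables of FPKM values (fragments scaled by transcript length and library size), one row per gene, and no read counts were used here. Per the submitters' processing notes, the authors called bases with CASAVA 1.4, aligned reads to hg38 with HISAT2 2.1.0 and computed the deposited FPKM with Cufflinks 2.2.1. The deposited p-value column of one table was made by the authors before deposit by a test not given in the sources used here, and it is used in no comparison. The labels describe a directional library kit and an rRNA-depleted library, sequenced on different HiSeq machines, without assigning samples to either. Each table lists 60595 genes, of which 58520 identifiers are in GENCODE 29, and 4479 clone-style symbols were replaced by their current names. One table holds 4940 blank rows, and genes whose quantification the authors' deposited status calls failed (FN1 in the drug table and 4 genes in the FOSL1 hairpin table) were left out. All 18 FPKM columns were assigned to samples and 0 were left over.

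Log2(FPKM+1) was compared with limma 3.58.1 (moderated by eBayes with a trend and robust fitting) for genes at 1 FPKM or more in at least 2 libraries, and genes with a Benjamini-Hochberg adjusted p below 0.05 count as called. The 8 drug libraries were fitted together and the P and R hairpin tables each on their own, with residual degrees of freedom of 4, 2 and 2 and prior degrees of freedom of 2.79, 3.57 and 3.38. The interaction of the LSD1 hairpin with the line was fitted over the 8 hairpin libraries of both tables, although the plan foresaw such a fit for counts only. R_shFosL1 sits in a table without controls and was described against R_shCtrl of another table, by a log2 difference of at least 1 with the libraries apart. Count models were not run, since the tables hold no counts. In simulated data of the same layout, limma called 81.8% of genes changed by 2 on the log2 scale for P_DT, 90.9% for P_shLSD1 and 92.4% for R_shLSD1, and 19.4%, 38.8% and 58.2% of genes changed by 1.

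Before the data were examined, the groups, comparisons, threshold, most alternatives and 26 gene lists with 6 cell type marker sets were chosen. Lists of at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and the gene a hairpin targets was left out of lists in its comparison. All 26 are named with their results in the P_DT comparison of the report, and the marker sets cover endothelial, erythroid, fibroblast, keratinocyte, leukocyte and melanocytic cells.

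Genes named in each comparison are KDM1A, FOSL1, TFRC, GPX4, SLC7A11, LDHA, DUSP6, AXL, EGFR, MITF and SOX10, then the 6 largest rises and 6 largest falls among other called genes with a symbol, libraries apart and at least 2 FPKM in the higher group, then up to 4 members per list with the smallest adjusted p. Members that kept their call in every leave-one-out fit were preferred as examples of lists. No fold is given for a gene listed at 0 in a group. The results of 5 genes that these rules name are not reported here. Steps of whole fragments, which give the depth, assuming fragments of 250 bases, were clear in 9 of 18 libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.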

Results

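RNA was sequenced from A375 cells, a human melanoma line that carries an activating BRAF mutation, in 18 samples that form 9 groups of 2. The letter P in a group's name is read here as the parental line and R as the line resistant to inhibitors of BRAF and MEK. Each line was treated with vehicle (P_DMSO, R_DMSO) or with 250 nM dabrafenib, a BRAF inhibitor, plus 10 nM trametinib, a MEK inhibitor (P_DT, R_DT). Each line was also given a control hairpin (P_shCtrl, R_shCtrl) or a hairpin against LSD1 (P_shLSD1, R_shLSD1), the histone demethylase encoded by KDM1A, and the R line a hairpin against the AP-1 subunit FOSL1 (R_shFosL1). The 18 libraries summed to 556410 FPKM (P_DT replicate 1) to 814364 FPKM (P_shCtrl replicate 1) and held 13921 to 15314 genes at 1 FPKM or more. Whole-fragment steps in the values, clear in 9 libraries, put their depth at 7.6 to 10.9 M fragments. Mitochondrially encoded mRNAs made up 5.64% to 16.3% of the total. Changes below are log2 fold changes on the log2(FPKM+1) scale ± standard error with limma's adjusted p, list medians are given with camera's adjusted p, and levels are mean FPKM ± SD over n = 2 libraries per group. Genes counted as higher or lower within a list, or as terms above or below 0, are those that passed limma. The labels do not say that the replicates are separate cultures, so the p-values may measure technical spread only.

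On hg38, KDM1A lies on chromosome 1 from 23019443 to 23083689, and FOSL1 on chromosome 11 from 65892049 to 65900573. TFRC, the transferrin receptor that takes up iron, lies on chromosome 3 from 196027183 to 196082189. GPX4, the peroxidase that detoxifies lipid peroxides, lies on chromosome 19 from 1103926 to 1106791, and SLC7A11, the cystine transporter, on chromosome 4 from 138164097 to 138242349. LDHA, the lactate dehydrogenase subunit, lies on chromosome 11 from 18394388 to 18408425, and DUSP6, an ERK phosphatase transcribed in response to ERK signalling, on chromosome 12 from 89347232 to 89353271. The receptor tyrosine kinase AXL lies on chromosome 19 from 41219203 to 41261766 and EGFR on chromosome 7 from 55019021 to 55211628. MITF and SOX10, transcription factors of the melanocyte lineage, lie on chromosome 3 from 69739435 to 69968337 and on chromosome 22 from 37970686 to 37987422. All 11 are protein-coding.

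In the P line, dabrafenib plus trametinib lowered the ERK phosphatase DUSP6 from 59.7 ± 4.65 FPKM in P_DMSO to 5.82 ± 0.548 FPKM in P_DT (-3.16 ± 0.15, adjusted p = 0.00014). The receptors AXL (-1.82 ± 0.18, adjusted p = 0.0013) and EGFR (-2.08 ± 0.24, 0.0022) and the cystine transporter SLC7A11 (-1.40 ± 0.18, 0.0035) fell, and MITF rose from 6.17 ± 1.90 to 26.5 ± 3.90 FPKM (1.96 ± 0.29, 0.0051). SOX10 rose (1.00 ± 0.17, adjusted p = 0.0087), while FOSL1 (-2.01 ± 0.41, 0.017) and KDM1A (-0.40 ± 0.11, 0.048) fell. Over protein-coding genes of mean 5 FPKM or more, the P_DMSO libraries lay further apart than other replicates (SD of the difference 0.60 against 0.26 to 0.38). FOSL1 was at 146 ± 96.0 FPKM in P_DMSO against 31.3 ± 2.36 FPKM in P_DT. TFRC (0.14 ± 0.12, adjusted p = 0.44), GPX4 (0.15 ± 0.16, 0.55) and LDHA (0.01 ± 0.13, 0.97) did not pass. The largest rises were in MOXD1, a monooxygenase (6.11 ± 0.32), ID3, an inhibitor of helix-loop-helix factors (5.97 ± 0.19), OLFML2A (5.96 ± 0.21), the matrix metalloproteinase MMP15 (5.51 ± 0.16), the matricellular protein CCN3 (4.91 ± 0.24) and the neural adhesion molecule LSAMP (4.65 ± 0.26). The largest falls were in the stress cytokine GDF15 (-6.77 ± 0.37), the cytokine IL24 (-6.59 ± 0.13), the proteoglycan ESM1 (-6.06 ± 0.23), the hair keratin KRT81 (-5.74 ± 0.22), the ecto-nucleotidase NT5E (-5.45 ± 0.18) and the Ras-induced TMEM158 (-5.29 ± 0.31).

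Of 21 tested MAPK pathway output genes, 17 fell and 1 rose under the drugs in P, with DUSP5 (-3.18 ± 0.13), the cyclin CCND1 (-2.56 ± 0.13) and PHLDA1 (-2.34 ± 0.12) among them. The MAPK output median was -2.30 (camera adjusted p = 3.6e-14, adjusted p = 0.048 with an estimated correlation). Of 21 genes of the ATF4 and unfolded protein response, which meets amino acid and protein-folding stress, 11 fell and 1 rose, such as TRIB3 (-3.20 ± 0.14) and MTHFD2 (-2.02 ± 0.15). The median of ATF4 genes was -0.99 (camera adjusted p = 5.0e-07, adjusted p = 0.048 at estimated correlation). Mitosis and G2/M genes fell in 10 of 22 and rose in none, with UBE2C (-1.28 ± 0.13) and TOP2A (-1.09 ± 0.14). The median of mitosis genes was -0.45 (camera adjusted p = 2.2e-05, adjusted p = 0.048 at estimated correlation). Among 10 replication-dependent histone genes 9 rose and 0 fell, such as H4C8 (3.83 ± 0.25) and the linker histone H1-2 (2.04 ± 0.24). The histone median was 2.03 (camera adjusted p = 3.9e-06, adjusted p = 0.048 at estimated correlation). Their mRNAs lack a poly(A) tail. Of other RNAs without one, RN7SK was at 5.58 and 0.0065 FPKM in P_DT against 73.2 and 13.3 FPKM in P_DMSO, RN7SL1 at 1332 and 1457 against 485 and 3227 FPKM, and RN7SL2 at 5670 and 4580 against 92.4 and 8392 FPKM. Adjusted over the list alone, 19 MAPK output genes, 15 ATF4 genes, 11 mitosis genes and 10 histone genes passed.

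The neural crest-like genes rose in 10 of 15 and fell in 1, with the adhesion molecule CADM1 (2.60 ± 0.13), the calcium-binding S100B (2.91 ± 0.19) and the receptor ERBB3 (1.93 ± 0.15). The neural crest-like median was 1.69 (camera adjusted p = 4.6e-05, 0.072 at estimated correlation). Interferon-stimulated genes rose in 11 of 24 and fell in 1, such as IFI6 (2.22 ± 0.19) and IFIT1 (1.42 ± 0.20). The interferon median was 0.80 (camera adjusted p = 0.001, 0.072 at estimated correlation). MHC class I presentation genes rose in 9 of 17, with the chaperone CALR (1.54 ± 0.16) and the isomerase PDIA3 (0.89 ± 0.11). The MHC class I median was 0.74 (camera adjusted p = 0.00061, 0.27 at estimated correlation). Mesenchymal and matrix genes rose in 11 of 21 and fell in 1, such as the collagen COL5A1 (2.91 ± 0.15) and SPARC (1.78 ± 0.11). The mesenchymal median was 0.70 (camera adjusted p = 0.003, 0.19 at estimated correlation). NF-kB targets and cytokines fell in 12 of 20 and rose in 2, with IL1B (-3.64 ± 0.21) and CXCL8 (-4.40 ± 0.30) against a rise of CCL2 (2.97 ± 0.29). The NF-kB median was -0.88 (camera adjusted p = 4.4e-06, 0.073 at estimated correlation). Cholesterol and lipid synthesis genes fell in 9 of 21 and rose in 1, with INSIG1 (-1.57 ± 0.15). The cholesterol median was -0.23 (camera adjusted p = 0.0036, 0.083 at estimated correlation). The p53 target genes fell in 7 of 19, with GADD45A (-2.65 ± 0.18). The p53 median was -0.16 (camera adjusted p = 0.0044, 0.21 at estimated correlation). DNA replication and G1/S genes fell in 5 of 24 and rose in 1. The median of replication genes was -0.25 (camera adjusted p = 0.0054, 0.26 at estimated correlation). Adjusted over the list alone, 12 neural crest-like, 15 interferon-stimulated, 11 MHC class I, 14 mesenchymal, 14 NF-kB, 11 cholesterol, 8 p53 and 6 replication genes passed.

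Cytosolic ribosomal protein genes fell in 12 of 26, and 14 adjusted over the list alone, with RPLP0 (-1.03 ± 0.13). The ribosomal median was -0.70 (camera adjusted p = 5.0e-07, 0.29 at estimated correlation). With quantile normalization the median was -0.24 and adjusted p = 0.11. Ferroptosis defence genes, which limit lipid peroxidation, fell in 7 of 21 and rose in 2, with the ferritin FTH1 (-1.49 ± 0.15) and the desaturase SCD (-1.01 ± 0.11), and 10 passed adjusted over the list alone. The ferroptosis defence median was -0.33 (camera adjusted p = 0.037, 0.18 at estimated correlation). That call ended without P_DMSO replicate 1 (adjusted p = 0.20), without P_DT replicate 2 (0.057), with quantile normalization (0.10) and with GC and length trends removed (0.059). Camera did not call the AP-1 family (5 higher and 2 lower of 16, adjusted p = 0.69), although JUN (4.59 ± 0.29), MAF (4.08 ± 0.32) and FOSL2 (2.36 ± 0.21) rose and MAFF (-2.31 ± 0.32) fell. Nor did it call the dedifferentiated AXL-high state (8 higher and 8 lower of 22, adjusted p = 0.55), with THBS1 (4.0 ± 0.12) and PLAUR (-2.33 ± 0.14). Melanocyte differentiation missed it too (7 higher and 3 lower of 12, adjusted p = 0.18), with the pigment enzyme DCT (4.10 ± 0.21). Lysosome and autophagy (8 higher and 5 lower of 20, adjusted p = 0.25), YAP/TEAD targets (4 and 6 of 22, 0.053) and receptor tyrosine kinases (4 and 6 of 19, 0.20) also did. So did oxidative phosphorylation (1 and 3 of 24, 0.063) and mitochondrially encoded mRNAs (2 and 0 of 13, 0.092). Ferroptosis promotion and iron uptake (2 and 3 of 16, 0.70), glycolysis and lactate transport (2 and 3 of 24, 0.18), the LSD1-CoREST complex (3 and 3 of 14, 0.84) and lysine lactylation writers and erasers (2 and 2 of 13, 0.69) missed it too. Median, mean and test did not share a sign for the AXL-high, ferroptosis promotion and LSD1-CoREST lists.

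Over 17190 tested genes, limma called 2199 higher and 1662 lower in P_DT than in P_DMSO, 3861 in all, of which 1447 rises and 911 falls were at least 2-fold. Quantile normalization moved the median of all genes from 0.106 to -0.0024 and gave 2013 higher and 2125 lower. The count was 6055 without P_DMSO replicate 2, 1207 without P_DT replicate 1 and 1179 without P_DT replicate 2, and 1447 with the libraries of the 2 groups alone. Leaving out P_DT replicate 1 or 2 ended the calls of KDM1A (adjusted p = 0.22 and 0.16), FOSL1 (0.081 and 0.096) and SOX10 (0.064 and 0.077), and KDM1A also lost its call without P_DMSO replicate 1 (0.056).

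In the R line the same drugs lowered DUSP6 from 34.3 ± 1.90 to 7.80 ± 0.946 FPKM (-2.01 ± 0.15, adjusted p = 0.0018) and TFRC from 122 ± 3.42 to 70.7 ± 0.809 FPKM (-0.78 ± 0.12, adjusted p = 0.016). KDM1A stood at 115 ± 0.521 FPKM in R_DT and 108 ± 5.30 FPKM in R_DMSO (0.09 ± 0.11, adjusted p = 0.70). FOSL1 (-0.53 ± 0.41, adjusted p = 0.48), GPX4 (0.36 ± 0.16, 0.23), SLC7A11 (0.61 ± 0.18, 0.10), LDHA (-0.27 ± 0.13, 0.28), AXL (-0.74 ± 0.18, 0.062), EGFR (-0.37 ± 0.24, 0.40) and MITF (0.75 ± 0.29, 0.17) did not pass. SOX10 was listed at 0 in both R_DMSO libraries and averaged 0.0817 FPKM in R_DT. The keratin KRT17 rose from 3.03 to 377 FPKM (6.56 ± 0.18), ahead of the actin-binding TAGLN (5.93 ± 0.19), the acute-phase protein SAA1 (5.91 ± 0.38), the natriuretic peptide precursor NPPB (5.25 ± 0.20), IGFBP7 (4.89 ± 0.34) and the lipase MGLL (4.87 ± 0.41). ESM1 fell (-4.33 ± 0.23), as did the noncoding RNAs BCYRN1, RMRP and LIPE-AS1, listed at 0 in R_DT against 9.72, 15.6 and 9.56 FPKM in R_DMSO, SCARNA12 (-3.38 ± 0.55) and SEPSECS-AS1 (-3.26 ± 0.29). Of RNAs without a poly(A) tail, RN7SL1 was at 2541 and 2165 FPKM in R_DT against 725 and 320 FPKM, RN7SL2 at 6563 and 7000 against 1219 and 353, and RN7SK at 9.79 and 7.77 against 32.8 and 16.5.

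Mitosis and G2/M genes fell in 16 of 22 and rose in none, such as UBE2C (-1.16 ± 0.13) and the cyclin CCNB1 (-1.44 ± 0.18). The mitosis median was -1.05 (adjusted p = 8.6e-15, 0.022 at estimated correlation). Genes of the dedifferentiated AXL-high state rose in 11 of 22 and fell in 2, with tenascin TNC (3.22 ± 0.14), TPM1 (2.51 ± 0.12) and the cytokine IL6 (2.77 ± 0.20). The AXL-high median was 0.82 (adjusted p = 2.1e-06, 0.062 at estimated correlation). MHC class I presentation genes rose in 9 of 17, with HLA-B (2.50 ± 0.18). The MHC class I median was 0.95 (adjusted p = 5.6e-07, 0.17 at estimated correlation). YAP/TEAD targets rose in 8 of 22 and fell in 1, with IGFBP3 (2.55 ± 0.14) and TGFB2 (3.11 ± 0.20). The YAP/TEAD median was 0.56 (adjusted p = 6.9e-06, 0.17 at estimated correlation). MAPK pathway output genes fell in 6 of 21. The MAPK output median was -0.55 (adjusted p = 0.0041, 0.21 at estimated correlation). Interferon-stimulated genes rose in 4 of 24, with BST2 (2.93 ± 0.20). The interferon median was 0.41 (adjusted p = 0.00025, 0.081 at estimated correlation). ATF4 genes rose in 2 of 21 and fell in 1. The ATF4 median was 0.52 (adjusted p = 0.00026, 0.081 at estimated correlation). Adjusted over the list alone, 20 mitosis, 16 AXL-high, 13 MHC class I, 15 YAP/TEAD, 8 MAPK output, 9 interferon and 10 ATF4 genes passed.

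DNA replication genes fell in 4 of 24. The replication median was -0.39 (adjusted p = 6.9e-06, 0.17 at estimated correlation). Lysosome and autophagy genes rose in 5 of 20. The lysosome median was 0.18 (adjusted p = 0.015, 0.23 at estimated correlation). The p53 target genes rose in 4 of 19. The p53 median was 0.35 (adjusted p = 0.0022, 0.19 at estimated correlation). Receptor tyrosine kinases rose in 2 of 19. The receptor tyrosine kinase median was 0.30 (adjusted p = 0.015, 0.17 at estimated correlation, 0.060 without R_DMSO replicate 2 and 0.095 with GC and length trends removed). Ferroptosis promotion genes rose in 3 of 16 and fell in 1. The ferroptosis promotion median was 0.14 (adjusted p = 0.039, 0.19 at estimated correlation, 0.11 without R_DMSO replicate 1 and 0.079 with every gene above 0 FPKM). Of 26 ribosomal protein genes none passed limma singly or adjusted over the list alone, with 9 at an unadjusted p under 0.05. The ribosomal median was 0.45 (adjusted p = 3.6e-05, 0.37 at estimated correlation). With quantile normalization the median was 0.07 and adjusted p = 0.46. Mesenchymal and matrix genes rose in 6 of 21 and fell in 2, with COL5A1 (2.62 ± 0.15), without a list call (adjusted p = 0.075). The other 12 lists, neural crest-like genes (adjusted p = 0.051) the nearest, were not called. Adjusted over the list alone, 8 replication, 6 lysosome, 4 p53, 5 receptor tyrosine kinase and 5 ferroptosis promotion genes passed.

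Limma called 627 genes higher and 487 lower in R_DT than in R_DMSO, 1114 in all. The count was 100 without R_DMSO replicate 1, 76 without R_DMSO replicate 2, 53 without R_DT replicate 1 and 69 without R_DT replicate 2. It was 2071 with GC and length trends removed, 625 with the replicate block and 2506 with the libraries of the 2 groups alone. In the same order of left-out libraries TFRC had adjusted p = 0.0998, 0.13, 0.14 and 0.13, UBE2C 0.071, 0.080, 0.092 and 0.057, and CCNB1 0.072, 0.097, 0.10 and 0.097. RMRP had adjusted p = 0.094, 0.14, 0.13 and 0.12, LIPE-AS1 0.073, 0.096, 0.092 and 0.084 and SCARNA12 0.12, 0.080, 0.12 and 0.14. SEPSECS-AS1 had adjusted p = 0.056 without R_DT replicate 1.

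Between the lines under vehicle, KDM1A was higher in R_DMSO than in P_DMSO (108 ± 5.30 against 55.9 ± 0.964 FPKM; 0.94 ± 0.11, adjusted p = 0.0018). LDHA (886 ± 24.6 against 217 ± 28.3 FPKM; 2.03 ± 0.13, adjusted p = 0.00018), TFRC (1.84 ± 0.12, 0.00017) and MITF (1.86 ± 0.29, 0.0045) were higher as well. SLC7A11 (-3.10 ± 0.18, adjusted p = 0.00012), AXL (-1.49 ± 0.18, 0.0019) and DUSP6 (-0.78 ± 0.15, 0.011) were lower, and SOX10 was listed at 0 in R_DMSO against 161 ± 26.7 FPKM in P_DMSO. FOSL1 (-0.26 ± 0.41, adjusted p = 0.68), GPX4 (0.38 ± 0.16, 0.12) and EGFR (-0.06 ± 0.24, 0.87) did not pass. The largest excesses in R_DMSO were in the membrane protein BASP1 (7.01 ± 0.28), the long noncoding RNAs UCA1 (6.83 ± 0.14) and LINC01764 (6.30 ± 0.58) and the cancer-testis antigen CTAG2 (6.48 ± 0.16). The lipoprotein receptor OLR1 and the deaminase CDA were listed at 0 in P_DMSO against 111 and 75.5 FPKM. Beside SOX10, the largest deficits were in the guidance factor SEMA3A (-6.67 ± 0.55), the calcium-binding S100A4 (-6.50 ± 0.21), IGFBP4 (-5.92 ± 0.25) and T-cadherin CDH13 (-5.85 ± 0.17), and follistatin FST was listed at 0 in R_DMSO against 58.6 FPKM.

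Cholesterol and lipid synthesis genes were higher in 18 of 21 and lower in none, with HMGCS1 (3.37 ± 0.13), MSMO1 (2.37 ± 0.15) and SQLE (1.91 ± 0.14). The cholesterol median was 1.38 (adjusted p = 3.1e-09, 0.03 at estimated correlation). Mitosis and G2/M genes were higher in 21 of 22, such as CDC20 (2.13 ± 0.15) and BUB1 (2.17 ± 0.18). The median of mitosis genes was 1.35 (adjusted p = 8.6e-12, 0.03 at estimated correlation). DNA replication genes were higher in 21 of 24, with RRM2 (3.20 ± 0.16) and TK1 (2.72 ± 0.16). The median of replication genes was 1.06 (adjusted p = 3.1e-09, 0.13 at estimated correlation). Glycolysis and lactate transport genes were higher in 17 of 24, with ALDOC (3.62 ± 0.23) and PGK1 (1.81 ± 0.12). The glycolysis median was 1.00 (adjusted p = 3.8e-07, 0.38 at estimated correlation). Mitochondrially encoded mRNAs were higher in 8 of 13. The mitochondrial mRNA median was 1.12 (adjusted p = 0.0035, 0.64 at estimated correlation). MAPK pathway output genes were lower in 12 of 21 and higher in 2, such as PHLDA1 (-2.06 ± 0.12), SPRY2 (-1.92 ± 0.15) and ETV4 (-2.82 ± 0.24). The MAPK output median was -0.80 (adjusted p = 2.6e-05, 0.13 at estimated correlation). Neural crest-like genes were lower in 8 of 15 and higher in 2, with ERBB3 (-2.38 ± 0.15) and NGFR (-3.04 ± 0.26). The neural crest-like median was -1.41 (adjusted p = 0.0014, 0.13 at estimated correlation). ATF4 genes were lower in 10 of 21 and higher in 3, with TRIB3 (-2.34 ± 0.14) lower and the chaperone HSPA5 (1.29 ± 0.11) higher. The median of ATF4 genes was -0.38 (adjusted p = 0.0032, 0.13 at estimated correlation). In all, 18 cholesterol, 22 mitosis, 22 replication, 17 glycolysis, 9 mitochondrial mRNAs, 15 MAPK output, 11 neural crest-like and 14 ATF4 genes passed adjusted over the list alone.

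NF-kB targets and cytokines were higher in 9 of 20 and lower in 4, with TNF (4.41 ± 0.19) and CXCL1 (2.36 ± 0.13) against IL1B (-3.60 ± 0.21). The NF-kB median was 0.77 (adjusted p = 0.039, 0.44 at estimated correlation, 0.057 without R_DMSO replicate 2, 0.052 with a pseudocount of 0.1 and 0.077 with 2 groups alone). Ribosomal protein genes were lower in 5 of 26 and in 0 adjusted over the list alone. The ribosomal median was -0.31 (adjusted p = 0.0068, 0.64 at estimated correlation). The list call ended without P_DMSO replicate 2 (0.11), without R_DMSO replicate 2 (0.068) and with quantile normalization (0.054). In the AXL-high list 10 genes were higher and 7 lower of 22, with TNC (-1.94 ± 0.14) (adjusted p = 0.48). Among YAP/TEAD targets 11 were higher and 5 lower of 22, with F3 (2.89 ± 0.26) and IGFBP3 (-4.58 ± 0.14) (adjusted p = 0.69). The other 14 lists had camera adjusted p-values from 0.31 to 0.86. Adjusted over the list alone, 16 NF-kB genes passed.

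Limma called 2777 genes higher and 1974 lower in R_DMSO than in P_DMSO, 4751 in all, and 2253 and 2309 with quantile normalization. The count was 2266 without R_DMSO replicate 1, 2269 without R_DMSO replicate 2 and 2529 with the libraries of the 2 groups alone, and DUSP6 lost its call without R_DMSO replicate 1 (adjusted p = 0.075) and replicate 2 (0.053). FOSL1 was called in opposite directions without P_DMSO replicate 1 (-0.98 ± 0.14, adjusted p = 0.0041) and without P_DMSO replicate 2 (0.47 ± 0.14, adjusted p = 0.043).

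Under the drugs the lines differed at KDM1A, with 115 ± 0.521 FPKM in R_DT against 42.2 ± 1.61 FPKM in P_DT (1.42 ± 0.11, adjusted p = 0.00022). LDHA (1.75 ± 0.13, adjusted p = 0.00018), TFRC (0.92 ± 0.12, 0.0015), EGFR (1.64 ± 0.24, 0.0025) and GPX4 (0.59 ± 0.16, 0.026) were higher in R_DT, and SLC7A11 was lower (-1.09 ± 0.18, 0.0044). SOX10 averaged 0.0817 FPKM in R_DT against 323 ± 14.7 FPKM in P_DT (adjusted p = 2.4e-06), whereas FOSL1 (1.22 ± 0.41, 0.056), DUSP6 (0.37 ± 0.15, 0.10), AXL (-0.41 ± 0.18, 0.12) and MITF (0.65 ± 0.29, 0.12) did not pass. Limma pools the spread over the 8 drug libraries. The standard error of FOSL1 thus takes in the P_DMSO libraries, which lay far apart at FOSL1 and are in neither group here. GDF15 led the genes higher in R_DT (1097 against 0.873 FPKM; 9.21 ± 0.37), followed by UCA1 (8.40 ± 0.14), KRT17 (8.34 ± 0.18), OLR1 (7.91 ± 0.15), the actin bundler LCP1 (7.78 ± 0.20) and C15orf48 (7.59 ± 0.25). HLA-DRA, an MHC class II chain, was listed at 0 in R_DT against 284 FPKM in P_DT, and CDH13 (-7.23 ± 0.17), CCN3 (-7.10 ± 0.24) and IGFBP4 (-6.98 ± 0.25) were far lower.

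Cholesterol and lipid synthesis genes were higher in 17 of 21, with MSMO1 (3.22 ± 0.15) and INSIG1 (2.76 ± 0.15). The cholesterol median was 1.52 (adjusted p = 5.1e-11, 0.037 at estimated correlation). Genes of the AXL-high state were higher in 17 of 22 and lower in 3, with IL6 (6.72 ± 0.20) against THBS1 (-2.33 ± 0.12). The AXL-high median was 1.63 (adjusted p = 5.4e-06, 0.045 at estimated correlation). Mitosis genes were higher in 19 of 22, with BUB1B (1.37 ± 0.13). The mitosis median was 0.96 (adjusted p = 2.6e-08, 0.037 at estimated correlation). ATF4 genes were higher in 13 of 21 and lower in 1, with MTHFD2 (1.98 ± 0.15). The ATF4 median was 0.90 (adjusted p = 2.8e-05, 0.045 at estimated correlation). All 10 histone genes were lower, also adjusted over the list alone, such as H4C8 (-4.23 ± 0.25). The histone median was -2.13 (adjusted p = 4.6e-06, 0.045 at estimated correlation). In all, 19 cholesterol, 20 AXL-high, 21 mitosis and 17 ATF4 genes passed adjusted over the list alone.

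Glycolysis genes were higher in 19 of 24, with the glucose transporter SLC2A3 (3.69 ± 0.13) and HK2 (2.07 ± 0.15). The glycolysis median was 1.1 (adjusted p = 2.6e-09, 0.15 at estimated correlation). NF-kB targets were higher in 13 of 20 and lower in 1, with CXCL8 (6.74 ± 0.30). The NF-kB median was 1.83 (adjusted p = 2.8e-06, 0.062 at estimated correlation). YAP/TEAD targets were higher in 15 of 22, with ANKRD1 (3.53 ± 0.18) and CCN1 (2.48 ± 0.15). The YAP/TEAD median was 0.68 (adjusted p = 2.7e-06, 0.13 at estimated correlation). DNA replication genes were higher in 18 of 24. The replication median was 0.93 (adjusted p = 2.7e-08, 0.062 at estimated correlation). The p53 targets were higher in 8 of 19, with RRM2B (1.60 ± 0.13). The p53 median was 0.71 (adjusted p = 0.00047, 0.14 at estimated correlation). Neural crest-like genes were lower in 9 of 15 and higher in 1, with S100B (-5.64 ± 0.19) and ERBB3 (-3.70 ± 0.15). The neural crest-like median was -1.84 (adjusted p = 2.7e-05, 0.062 at estimated correlation). MAPK output genes were higher in 7 of 21 and lower in 4, with DUSP5 (2.94 ± 0.13) and CCND1 (1.78 ± 0.13). The MAPK output median was 0.37 (adjusted p = 0.039, 0.30 at estimated correlation, 0.070 without P_DT replicate 1 and 0.051 without R_DT replicate 1). In all, 19 glycolysis, 14 NF-kB, 18 YAP/TEAD, 20 replication, 8 p53, 12 neural crest-like and 14 MAPK output genes passed adjusted over the list alone.

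Ferroptosis defence genes were higher in 9 of 21 and lower in 4, with TXNRD1 (1.87 ± 0.13). The ferroptosis defence median was 0.57 (adjusted p = 0.039, 0.15 at estimated correlation). The list call ended without P_DT replicate 1 (0.058), P_DT replicate 2 (0.067) or R_DT replicate 2 (0.051) and with quantile normalization (0.19). Ribosomal protein genes were higher in 16 of 26. The ribosomal median was 0.83 (adjusted p = 4.6e-06, 0.30 at estimated correlation). With quantile normalization the median was 0.08 and adjusted p = 0.99. MHC class I genes were higher in 8 of 17 and lower in 1. The MHC class I median was 0.67 (adjusted p = 0.027, 0.41 at estimated correlation, 0.058 without P_DT replicate 1 and 0.18 with quantile normalization). Oxidative phosphorylation genes were higher in 6 of 24. The oxidative phosphorylation median was 0.35 (adjusted p = 0.012, 0.25 at estimated correlation, 0.062 without P_DT replicate 1 and 0.34 with quantile normalization). Lysine lactylation genes were higher in 2 and lower in 5 of 13, with the alanyl-tRNA synthetase AARS1 (1.1 ± 0.14) and the deacetylase SIRT2 (-1.72 ± 0.22), without a list call (adjusted p = 0.14). Ferroptosis promotion genes were higher in 6 of 16 and lower in 1, with ACSL4 (2.48 ± 0.20) (adjusted p = 0.076). In the AP-1 list MAF was lower (-5.77 ± 0.32), and the other lists had adjusted p-values from 0.14 to 0.89. In all, 14 ferroptosis defence, 17 ribosomal, 10 MHC class I and 6 oxidative phosphorylation genes passed adjusted over the list alone.

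Limma called 3199 genes higher and 3263 lower in R_DT than in P_DT, 6462 in all. The count was 3551, 3592, 3599 and 3668 without P_DT replicate 1, P_DT replicate 2, R_DT replicate 1 and R_DT replicate 2. The call of GPX4 ended without P_DT replicate 1 (adjusted p = 0.15), R_DT replicate 1 (0.10) or R_DT replicate 2 (0.13) and with quantile normalization (0.17). Set beside the drug response of P, 1360 genes rose in P_DT and were lower in R_DT than in P_DT, 961 fell and were higher, 2321 in all, and 209 went the same way. OLFML2A (5.96 and -4.79) and the transcription factor NFATC2 (4.22 and -4.55) are among the former, GDF15 (-6.77 and 9.21), CXCL8 (-4.40 and 6.74) and KRT81 (-5.74 and 4.38) among the latter. Both comparisons use P_DT with opposite signs, so no chance level holds. A drug effect that R lacks, or noise in P_DT, may give such genes. Simulated groups sharing P_DT, with no gene changed, gave a mean correlation across genes of -0.50 and a covariance of -0.058, against -0.53 and -0.51 here. The count was 696 without P_DT replicate 1, 721 without P_DT replicate 2, 1041 with 2 groups alone and 1259 for folds of at least 1.

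Tested as an interaction, the drug response of R differed from that of P at SLC7A11 (2.01 ± 0.26, adjusted p = 0.0061), EGFR (1.71 ± 0.34, 0.023), DUSP6 (1.15 ± 0.22, 0.019), AXL (1.08 ± 0.26, 0.038) and TFRC (-0.92 ± 0.17, 0.017), a positive value meaning a larger rise or smaller fall in R. KDM1A (0.48 ± 0.16, adjusted p = 0.094), FOSL1 (1.48 ± 0.58, 0.14), GPX4 (0.21 ± 0.22, 0.56), LDHA (-0.28 ± 0.19, 0.37), MITF (-1.21 ± 0.40, 0.095) and SOX10 (adjusted p = 0.054, listed at 0 in R_DMSO) did not pass. The largest positive terms were those of GDF15 (8.72 ± 0.53), KRT81 (8.28 ± 0.31), KRT17 (7.35 ± 0.25), MGLL (6.58 ± 0.58) and SAA1 (5.98 ± 0.53). The iron-binding lipocalin LCN2 followed, listed at 0 in R_DMSO and P_DT against 11.8 FPKM in R_DT and 16.3 FPKM in P_DMSO. The largest negative terms were those of RMRP (listed at 0 in R_DT), SCARNA12 (listed at 0 in P_DMSO), the small nucleolar host gene SNHG9 (-4.75 ± 1.23), LSAMP (-4.68 ± 0.36), the growth factor PTN (-4.58 ± 0.34) and the histone HIST2H2BE (-4.43 ± 0.41).

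MAPK output genes passed in 14 above and 1 below 0 of 21, with CCND1 (3.08 ± 0.18) and DUSP5 (2.47 ± 0.19). The MAPK output median was 1.62 (adjusted p = 1.8e-10, 0.052 at estimated correlation). ATF4 genes passed in 12 above and 1 below of 21, with TRIB3 (3.29 ± 0.20). The median of ATF4 genes was 1.18 (adjusted p = 9.0e-10, 0.052 at estimated correlation). AXL-high genes passed in 13 above and 2 below of 22, with NT5E (4.5 ± 0.25). The AXL-high median was 1.1 (adjusted p = 1.5e-06, 0.052 at estimated correlation). YAP/TEAD targets passed in 12 above and 1 below of 22, with IGFBP3 (4.97 ± 0.20). The YAP/TEAD median was 0.80 (adjusted p = 8.4e-07, 0.11 at estimated correlation). NF-kB targets passed in 9 above and 1 below of 20, with CXCL8 (4.53 ± 0.42). The NF-kB median was 1.15 (adjusted p = 1.5e-06, 0.091 at estimated correlation). The p53 targets passed in 8 of 19 above 0, with GADD45A (3.22 ± 0.26) and the cell cycle inhibitor CDKN1A (2.58 ± 0.36). The p53 median was 1.03 (adjusted p = 3.5e-05, 0.11 at estimated correlation). Receptor tyrosine kinases passed in 7 above and 2 below of 19, with EPHA2 (2.80 ± 0.29). The receptor tyrosine kinase median was 0.43 (adjusted p = 0.01, 0.11 at estimated correlation). Histones passed in 7 of 10 below 0, with H4C8 (-3.73 ± 0.35). The histone median was -2.20 (adjusted p = 5.5e-06, 0.052 at estimated correlation). Neural crest-like genes passed in 7 of 15 below 0. The neural crest-like median was -1.32 (adjusted p = 0.00059, 0.11 at estimated correlation). In all, 15 MAPK output, 17 ATF4, 16 AXL-high, 14 YAP/TEAD, 14 NF-kB, 8 p53, 11 receptor tyrosine kinase, 10 histone and 11 neural crest-like genes passed adjusted over the list alone.

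Ribosomal protein genes passed in 14 of 26 above 0. The ribosomal median was 1.13 (adjusted p = 2.7e-10, 0.20 at estimated correlation). Under quantile normalization it was 0.34 (adjusted p = 0.098). Mitosis genes passed in 3 of 22 below 0. The median of mitosis genes was -0.46 (adjusted p = 0.016, 0.11 at estimated correlation, 0.058 without P_DMSO replicate 2, 0.057 without R_DMSO replicate 2 and 0.098 under quantile normalization). The AP-1 list (adjusted p = 0.93) had a median of 0.15, a mean of -0.29 and a downward test, with JUN at -3.67 ± 0.42, and LSD1-CoREST (0.93) and lysosome genes (0.85) also differed in sign between median, mean and test. The ferritin FTH1 passed (2.13 ± 0.21) in the ferroptosis defence list, which did not (adjusted p = 0.075), and the other lists had adjusted p-values from 0.067 for cholesterol synthesis to 0.84 for replication. In all, 16 ribosomal and 5 mitosis genes passed adjusted over the list alone.

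Limma called 1141 interaction terms above and 1244 below 0, 2385 in all, and quantile normalization moved the median of all genes from -0.157 to -0.0249 and gave 1356 above and 1087 below. The count was 4521 (1555 above and 2966 below) without P_DMSO replicate 2, 676 and 646 without P_DT replicates 1 and 2, 801 and 792 without R_DMSO replicates 1 and 2, and 702 and 703 without R_DT replicates 1 and 2. For those 6 libraries from P_DT replicate 1 on, the adjusted p of TFRC became 0.078, 0.075, 0.064, 0.074, 0.086 and 0.081, of DUSP6 0.062, 0.082, 0.079, 0.067, 0.084 and 0.056, of AXL 0.12, 0.12, 0.075, 0.12, 0.13 and 0.12 and of EGFR 0.071, 0.090, 0.073, 0.085, 0.086 and 0.084. Between the drug responses themselves 291 genes went the same way in both lines against 127 by chance and 147 the opposite way against 123, with a correlation across genes, which are not independent replicates, of 0.11. COL5A1 (2.91 in P and 2.62 in R) and THBS1 (4.0 and 2.27) rose in both, and ESM1 (-6.06 and -4.33) and the neurosecretory protein VGF (-4.83 and -2.42) fell in both.

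**Figure D1:**
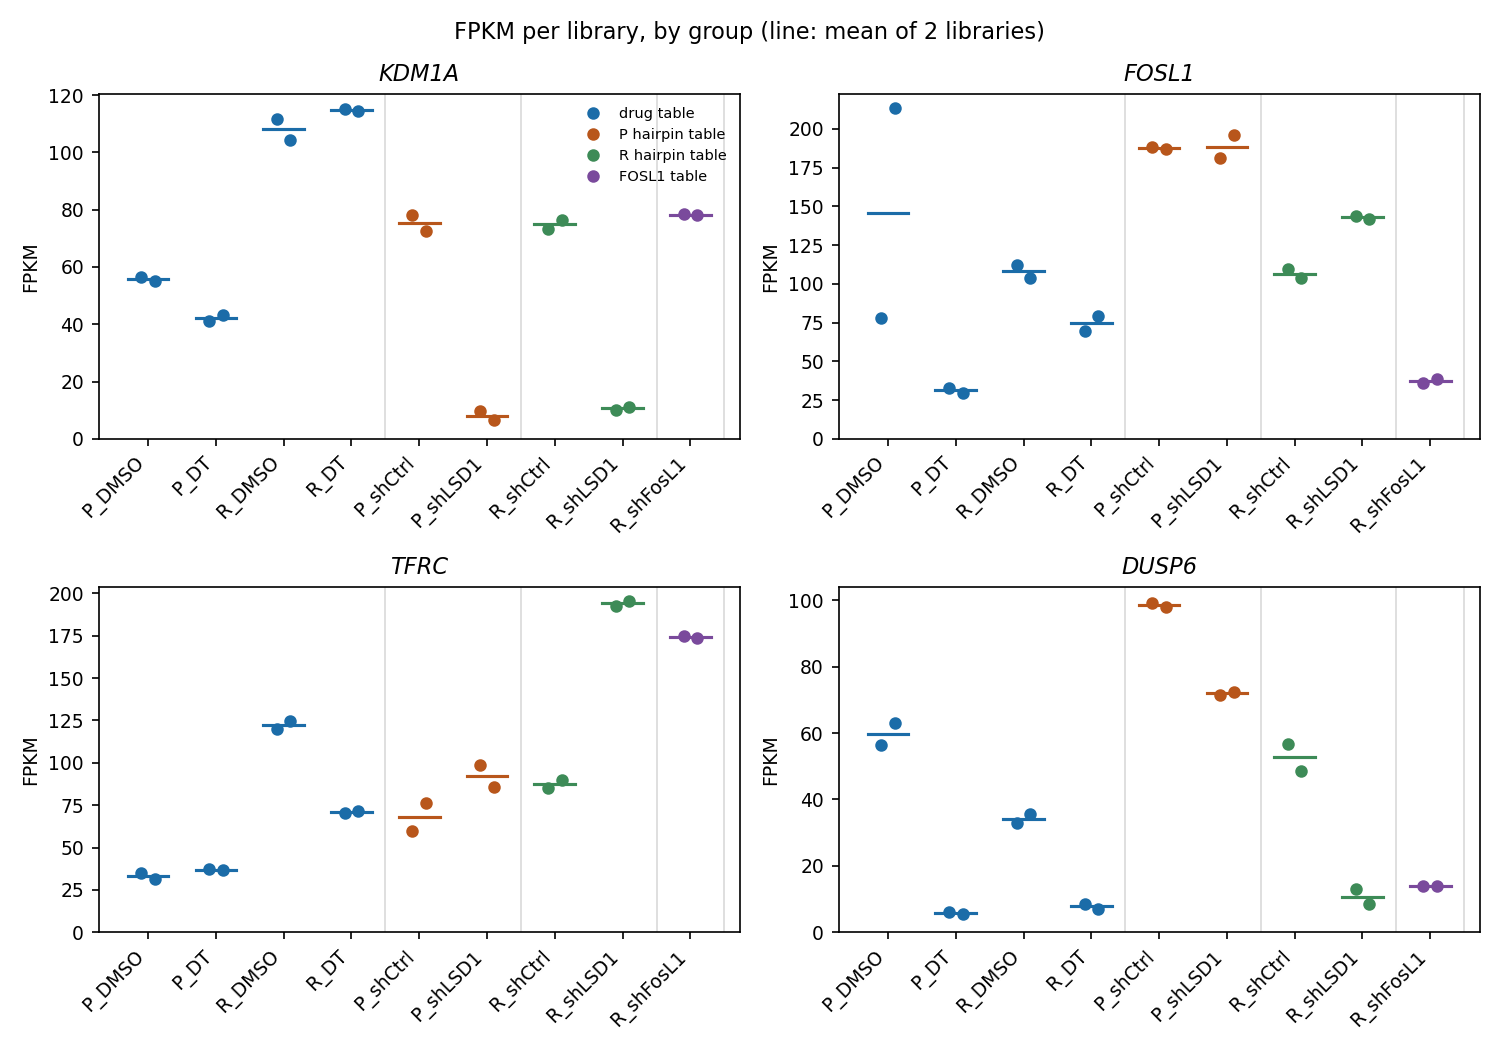
FPKM (y axis) of single libraries (points) and group means (lines, n = 2) for KDM1A, FOSL1, TFRC and DUSP6, by group (x axis). DUSP6 is low in both drug-treated groups, R_shLSD1 and R_shFosL1, KDM1A is low in both LSD1 hairpin groups, and levels set across the separately processed tables were not tested.

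**Figure D2:**
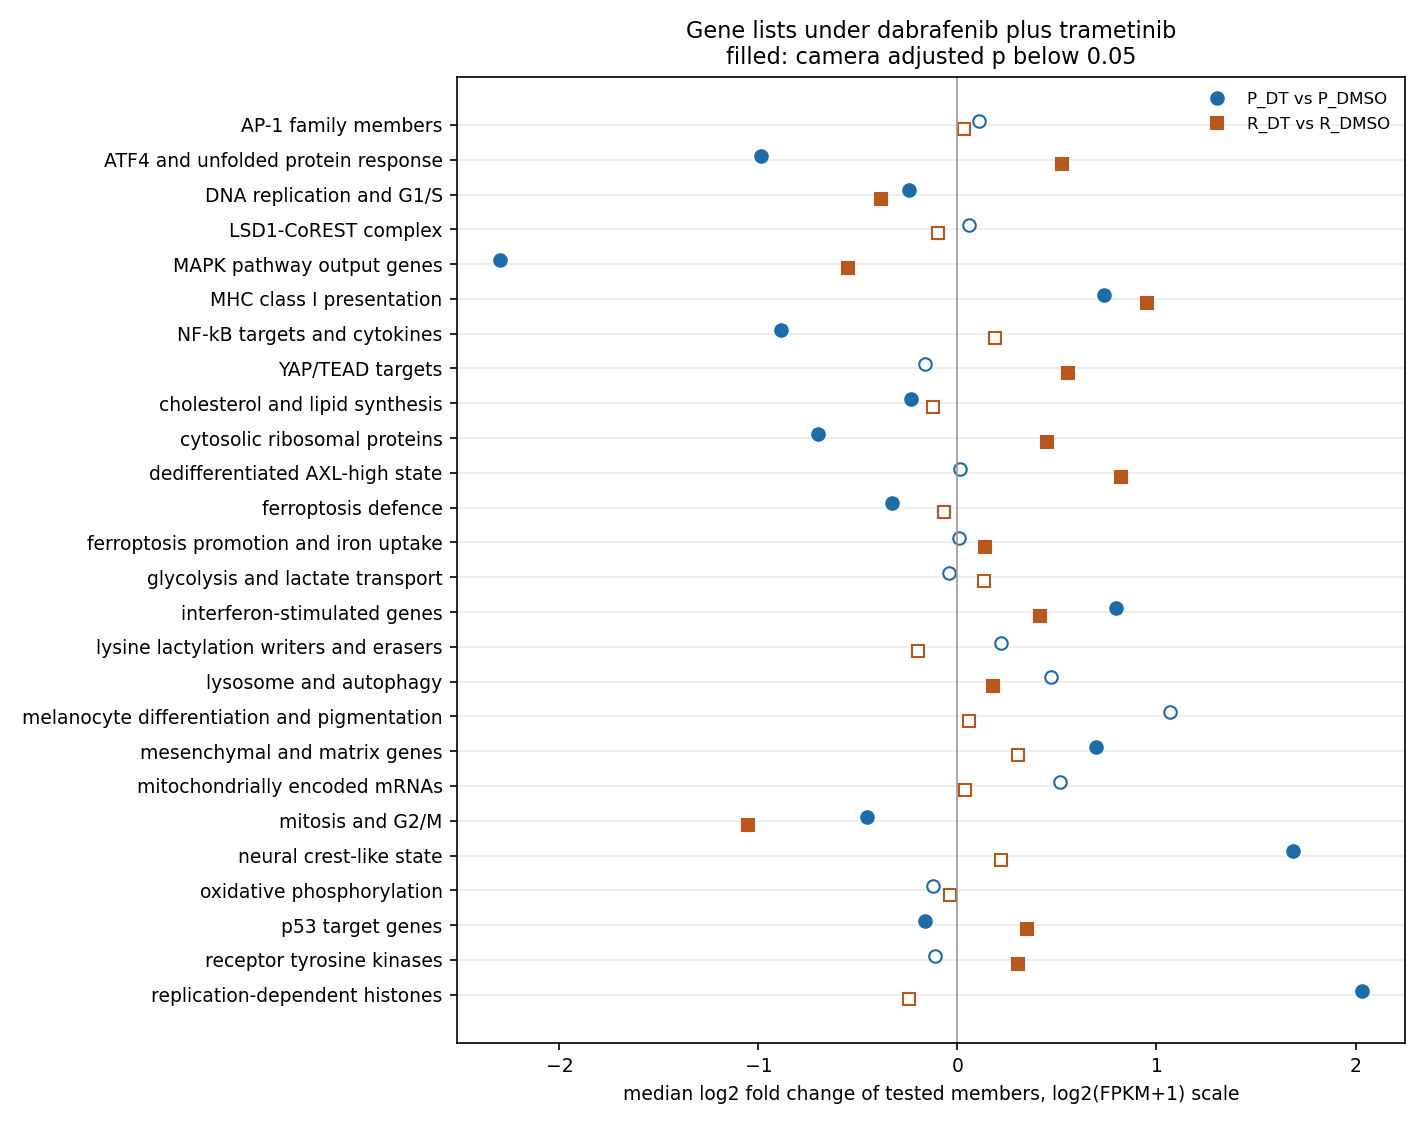
Median log2 fold change of the tested members of each gene list (x axis, log2(FPKM+1) scale) in the drug-table comparisons, with filled symbols where camera's adjusted p is below 0.05. MAPK pathway output genes lie far to the left for P_DT against P_DMSO, and ribosomal protein medians shrink towards 0 under quantile normalization (-0.24 for P_DT against P_DMSO).

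The LSD1 hairpin lowered its target in the P line from 75.2 ± 4.03 FPKM of KDM1A in P_shCtrl to 8.13 ± 1.99 FPKM in P_shLSD1 (-3.08 ± 0.20, adjusted p = 0.016). SOX10 rose from 94.2 ± 7.26 to 192 ± 10.4 FPKM (1.02 ± 0.17, adjusted p = 0.044). FOSL1 (0.00 ± 0.17, adjusted p = 0.99), TFRC (0.44 ± 0.19, 0.23), GPX4 (-0.12 ± 0.28, 0.83), SLC7A11 (0.48 ± 0.28, 0.35), LDHA (-0.09 ± 0.20, 0.83), DUSP6 (-0.45 ± 0.15, 0.14), AXL (-0.08 ± 0.18, 0.82), EGFR (-0.32 ± 0.34, 0.60) and MITF (-0.16 ± 0.21, 0.68) did not pass. The lipid phosphatase PLPP4 (3.79 ± 0.31), the small nucleolar RNA SNORD3C (3.38 ± 0.36), the secretory-granule protein PTPRN (3.36 ± 0.23), the proteoglycan lumican LUM (3.14 ± 0.33), the cytokine IL11 (3.12 ± 0.15) and VGF (3.03 ± 0.22) rose most. The integrin ITGB4 (-2.49 ± 0.17), the interleukin receptor IL1RL1 (-2.28 ± 0.19), the endoplasmic reticulum protein EI24 (-2.26 ± 0.14) and the glutathione-degrading CHAC1 (-2.25 ± 0.25) fell most after KDM1A, and C16orf95-DT was listed at 0 in P_shLSD1 against 4.08 FPKM.

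Genes of the AXL-high state rose in 5 of 22, with TNC (2.89 ± 0.25) and NT5E (1.74 ± 0.15). The AXL-high median was 0.33 (adjusted p = 0.0039, 0.60 at estimated correlation). Mesenchymal and matrix genes rose in 5 of 20 and fell in 1, with the integrin ITGA5 (1.89 ± 0.15) and COL5A1 (2.16 ± 0.28). The mesenchymal median was 0.63 (adjusted p = 0.00032, 0.60 at estimated correlation). Of 24 DNA replication and G1/S genes 3 fell and 21 did so adjusted over the list alone. The median of replication genes was -0.72 (adjusted p = 4.7e-10, 0.60 at estimated correlation). Lysosome and autophagy genes rose in 2 of 19, with GABARAPL1 (1.2 ± 0.14). The lysosome median was 0.59 (adjusted p = 3.5e-05, 0.60 at estimated correlation). Melanocyte differentiation genes rose in 2 of 10, with GPNMB (1.60 ± 0.14). The melanocyte median was 0.33 (adjusted p = 0.0057, 0.60 at estimated correlation). Mitochondrially encoded mRNAs passed limma in 0 of 13, with 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The mitochondrial mRNA median was 0.70 (adjusted p = 0.0043, 0.73 at estimated correlation). Mitosis genes passed limma in 0 of 22, with 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The mitosis median was -0.17 (adjusted p = 0.034, 0.60 at estimated correlation). Of 13 neural crest-like genes ERBB3 rose (2.09 ± 0.16) and SOX9 fell (-2.0 ± 0.21), and 6 passed adjusted over the list alone. The neural crest-like median was 0.27 (adjusted p = 0.039, 0.60 at estimated correlation). Without P_shCtrl replicate 1, P_shCtrl replicate 2, P_shLSD1 replicate 1 or P_shLSD1 replicate 2 the mitosis list had adjusted p = 0.065, 0.12, 0.077 and 0.17. The mitochondrial list had adjusted p = 0.20, 0.077 and 0.087 without the last 3 of these. The neural crest list had adjusted p = 0.12, 0.070 and 0.061 without P_shCtrl replicate 1, P_shLSD1 replicate 1 or P_shLSD1 replicate 2, 0.086 with every gene above 0 FPKM and 0.052 with a crossed replicate block. Quantile normalization gave 0.098 for it and 0.10 for mitosis. In all, 8 AXL-high, 11 mesenchymal, 10 lysosome and 3 melanocyte genes passed adjusted over the list alone.

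ATF4 genes fell in 5 of 21, with ASNS (-1.52 ± 0.18), without a list call (adjusted p = 0.11), and the ferroptosis promotion list held a rise of the polyamine acetyltransferase SAT1 (2.44 ± 0.17) (1 higher and 2 lower of 15, 0.35). Glycolysis genes were mixed, with PFKFB4 (1.85 ± 0.19) and HK2 (-1.52 ± 0.21) (2 higher and 2 lower, adjusted p = 0.54). The camera adjusted p was 0.20 for MAPK output genes, of which 0 of 21 passed limma and 9 had an unadjusted p under 0.05. The other lists had adjusted p-values from 0.053 for histones to 0.95 for ferroptosis defence. Limma called 324 genes higher and 180 lower of 14729, 504 in all. The count was 950 without P_shCtrl replicate 2, 271 without P_shLSD1 replicate 1, 305 without P_shLSD1 replicate 2, 879 with quantile normalization, 1347 with GC and length trends removed and 3446 (1570 higher and 1876 lower) with a crossed replicate block. With every gene above 0 FPKM tested, limma called 0 of 25913, 3969 had an unadjusted p under 0.05 and KDM1A had adjusted p = 0.073. SOX10 lost its call without P_shCtrl replicate 2 or either P_shLSD1 library.

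In the R line the hairpin lowered KDM1A from 74.9 ± 2.27 FPKM in R_shCtrl to 10.6 ± 0.731 FPKM in R_shLSD1 (-2.71 ± 0.10, adjusted p = 0.00094). DUSP6 fell from 52.7 ± 5.67 to 10.8 ± 3.03 FPKM (-2.21 ± 0.20, adjusted p = 0.0036) and TFRC rose from 87.7 ± 3.46 to 194 ± 2.04 FPKM (1.14 ± 0.06, adjusted p = 0.0013). Smaller rises were called for FOSL1 (0.42 ± 0.06, adjusted p = 0.01), AXL (0.43 ± 0.07, 0.016) and MITF (0.58 ± 0.11, 0.024). Falls were called for SLC7A11 (-0.75 ± 0.19, adjusted p = 0.044) and LDHA (-0.34 ± 0.04, 0.0074). GPX4 (-0.08 ± 0.07, 0.43) and EGFR (0.01 ± 0.14, 0.96) did not pass and SOX10 was listed at 0. The readthrough gene NDUFC2-KCTD14 (4.02 ± 0.85), the macrophage elastase MMP12 (3.98 ± 0.20), NPPB (3.06 ± 0.31), the carboxypeptidase CPA4 (3.03 ± 0.35), ZNF114 (2.92 ± 0.24) and the glutamate transporter SLC1A3 (2.71 ± 0.26) rose most. The lipolysis inhibitor G0S2 (-3.63 ± 0.19), CHAC1 (-3.09 ± 0.15), GDF15 (-2.47 ± 0.08), EI24 (-2.38 ± 0.09) and MAT2B, a subunit in S-adenosylmethionine synthesis (-2.38 ± 0.16), fell most beside KDM1A.

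ATF4 genes fell in 15 of 21 and rose in 2, with MTHFD2 (-1.2 ± 0.06), DDIT4 (-1.88 ± 0.12) and DDIT3 (-2.17 ± 0.15). The ATF4 median was -0.75 (adjusted p = 1.1e-05, 0.41 at estimated correlation). NF-kB targets and cytokines fell in 14 of 19 and rose in none, with CXCL8 (-2.30 ± 0.06), CXCL1 (-2.28 ± 0.10) and TNF (-1.36 ± 0.13). The NF-kB median was -1.02 (adjusted p = 3.5e-06, 0.41 at estimated correlation). YAP/TEAD targets rose in 10 of 22 and fell in 3, with CCN1 (1.62 ± 0.06), CCN2 (1.41 ± 0.09) and ANKRD1 (2.65 ± 0.14). The YAP/TEAD median was 0.40 (adjusted p = 0.0002, 0.41 at estimated correlation). Lysosome genes rose in 8 of 19 and fell in 1, with the autophagy receptor SQSTM1 (1.07 ± 0.05). The lysosome median was 0.24 (adjusted p = 0.0027, 0.41 at estimated correlation). Mitochondrially encoded mRNAs rose in 8 of 13 and fell in 1, with MT-ND6 (1.21 ± 0.05). The mitochondrial mRNA median was 0.22 (adjusted p = 0.00042, 0.41 at estimated correlation). The p53 targets fell in 8 of 19 and rose in 1, with the repair factor XPC (-1.98 ± 0.12), MDM2 (-1.35 ± 0.11) and BAX (-0.75 ± 0.06). The p53 median was -0.27 (adjusted p = 0.017, 0.41 at estimated correlation). Mitosis genes fell in 8 of 22, with TPX2 (-0.67 ± 0.07). The median of mitosis genes was -0.30 (adjusted p = 0.0031, 0.41 at estimated correlation). Replication genes fell in 6 of 24, with MCM2 (-0.83 ± 0.07). The replication median was -0.24 (adjusted p = 0.0081, 0.41 at estimated correlation). Interferon-stimulated genes fell in 4 of 18. The interferon median was -0.59 (adjusted p = 0.017, 0.53 at estimated correlation, 0.092 without R_shCtrl replicate 2 and 0.13 without R_shLSD1 replicate 2). In all, 19 ATF4, 17 NF-kB, 16 YAP/TEAD, 10 lysosome, 9 mitochondrial mRNAs, 9 p53, 10 mitosis, 13 replication and 4 interferon genes passed adjusted over the list alone.

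The MAPK output list was not called (4 higher and 5 lower of 20, adjusted p = 0.97): IER3 (-1.61 ± 0.07) and PHLDA1 (-1.60 ± 0.09) fell with DUSP6 while CCND1 rose (0.60 ± 0.06). In the AXL-high list 9 genes rose and 5 fell of 21, with TNC (1.42 ± 0.08) (adjusted p = 0.091). In the mesenchymal list 6 rose and 5 fell of 21, with SPARC (1.54 ± 0.07), the protease MMP3 (2.33 ± 0.16) and vimentin VIM (-0.80 ± 0.04) (adjusted p = 0.70). Ferroptosis defence genes rose in 4 of 20 and fell in 2, with the ferritins FTH1 (1.07 ± 0.05) and FTL (0.71 ± 0.05) (adjusted p = 0.32). Ferroptosis promotion genes rose in 3 of 17 and fell in 2, with ACSL4 (1.08 ± 0.10) (adjusted p = 0.15). Glycolysis genes rose in 8 of 24 and fell in 3, with SLC2A3 (0.86 ± 0.06) (adjusted p = 0.22). Lactylation genes fell in 4 of 13, with AARS1 (-0.82 ± 0.07) and the deacetylase HDAC2 (-0.81 ± 0.09) (adjusted p = 0.32). AP-1 genes rose in 5 of 15 and fell in 3, with JUN (0.98 ± 0.07) and JUNB (-1.11 ± 0.07) (adjusted p = 0.71). The other lists had adjusted p-values from 0.097 for ribosomal proteins to 0.91 for cholesterol synthesis, and the 4 measured histone genes were too few to test (median 0.03). Median, mean and test did not share a sign for the AP-1, glycolysis, MAPK output, melanocyte, MHC class I and oxidative phosphorylation lists.

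Limma called 1347 genes higher and 1771 lower in R_shLSD1 than in R_shCtrl of 14293, 3118 in all, and 1556 and 1514 with quantile normalization. The count was 966 and 1212 without R_shCtrl replicates 1 and 2, 1439 and 1398 without R_shLSD1 replicates 1 and 2, and 1609 when every gene above 0 FPKM was tested. SLC7A11, AXL and MITF lost their calls with any 1 of these libraries left out. FOSL1 lost its call without R_shCtrl replicate 2 or R_shLSD1 replicate 1, LDHA without R_shLSD1 replicate 1 and NDUFC2-KCTD14 without either R_shLSD1 library.

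Among 13250 genes tested in both lines, 240 changed the same way with the LSD1 hairpin (146 higher and 94 lower) against 46.3 by chance and 20 the opposite way against 50.5, with no library in common and a correlation across genes of 0.41. The matrix cytokine SPP1 (2.66 in P and 2.31 in R), VGF (3.03 and 2.29), TMEM45A (2.39 and 2.2) and the receptor decoy BAMBI (1.81 and 1.97) rose in both lines. EI24 (-2.26 and -2.38), CHAC1 (-2.25 and -3.09), MAT2B (-2.13 and -2.38), the RNA-binding SSB (-2.12 and -2.29) and prothymosin PTMA (-1.92 and -2.10) fell in both.

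The difference between the lines in the response to the LSD1 hairpin was tested over the 8 hairpin libraries together. DUSP6 fell further in R than in P (interaction -1.76 ± 0.25, adjusted p = 0.023), and the interaction term of KDM1A itself was 0.37 ± 0.23 (adjusted p = 0.47). TFRC (0.70 ± 0.20, adjusted p = 0.14), SLC7A11 (-1.23 ± 0.35, 0.13), FOSL1 (0.42 ± 0.14, 0.20), GPX4 (0.04 ± 0.32, 0.97), LDHA (-0.26 ± 0.17, 0.49), AXL (0.51 ± 0.16, 0.18), EGFR (0.34 ± 0.40, 0.74), MITF (0.74 ± 0.24, 0.18) and SOX10 (adjusted p = 0.050, listed at 0 in R) did not pass. The cardiac ankyrin repeat gene ANKRD1 (3.90 ± 0.23), CPA4 (3.34 ± 0.40), ZNF114 (3.01 ± 0.35) and the transcription factor KLF2 (2.68 ± 0.36) had the largest positive terms, beside MMP12, listed at 0 in P_shCtrl, and NPPB, listed at 0 in P. IL11 (-4.45 ± 0.16), SNORD3C (-4.12 ± 0.51), PMEPA1 (-4.08 ± 0.31), MYEOV (-3.93 ± 0.29) and IL1A (-3.73 ± 0.24) had the largest negative terms, beside G0S2, listed at 0 in P.

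Interaction terms of NF-kB targets passed in 8 of 20 below 0 and none above, with CXCL8 (-2.44 ± 0.18). The NF-kB median was -1.19 (adjusted p = 1.0e-12, 0.067 at estimated correlation). YAP/TEAD targets passed in 5 above and 1 below of 22, with CCN1 (2.38 ± 0.17) and NT5E (-2.37 ± 0.16). The YAP/TEAD median was 0.48 (adjusted p = 6.4e-05, 0.092 at estimated correlation). Mesenchymal genes passed in 4 of 22 below 0. The mesenchymal median was -0.45 (adjusted p = 0.00071, 0.092 at estimated correlation). The p53 targets passed in 2 of 19 below 0. The p53 median was -0.50 (adjusted p = 0.0002, 0.092 at estimated correlation). None of 24 replication genes passed limma singly, with 11 at an unadjusted p under 0.05 and 8 adjusted over the list alone. The median of replication genes was 0.49 (adjusted p = 2.8e-07, 0.094 at estimated correlation). ATF4 genes passed in 3 of 21 below 0, with DDIT4 (-2.49 ± 0.23). The median of ATF4 genes was -0.42 (adjusted p = 0.024, 0.41 at estimated correlation, 0.065 without P_shCtrl replicate 2, 0.053 without P_shLSD1 replicate 2 and 0.057 without R_shCtrl replicate 1). None of 23 interferon-stimulated genes passed limma singly, with 5 at an unadjusted p under 0.05. The interferon median was -0.40 (adjusted p = 0.022, 0.30 at estimated correlation). That list call ended without P_shCtrl replicate 2 (0.058), P_shLSD1 replicate 1 (0.091) and R_shLSD1 replicate 2 (0.094). None of 19 lysosome genes passed limma singly, with 8 at an unadjusted p under 0.05 and 5 adjusted over the list alone. The lysosome median was -0.42 (adjusted p = 0.017, 0.41 at estimated correlation). The lysosome call ended without P_shCtrl replicate 2 (0.074) and P_shLSD1 replicate 2 (0.068). In all, 16 NF-kB, 6 YAP/TEAD, 9 mesenchymal, 4 p53 and 13 ATF4 genes passed adjusted over the list alone.

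No other list was called in this interaction: adjusted p was 0.13 for AXL-high genes (4 passed above and 4 below 0), 0.18 for MAPK output genes (3 passed below and 0 above, with PHLDA1 at -1.54 ± 0.14) and from 0.089 for melanocyte differentiation to 0.88 for mitosis elsewhere. Limma called 103 terms above and 200 below 0 of 16075, 303 in all, 84 when every gene above 0 FPKM was tested and 595 with GC and length trends removed. The count was 132 and 135 without P_shCtrl replicates 1 and 2, 52 and 62 without P_shLSD1 replicates 1 and 2, 44 and 31 without R_shCtrl replicates 1 and 2 and 37 and 54 without R_shLSD1 replicates 1 and 2. DUSP6 lost its call in the first 6 of these fits and without R_shLSD1 replicate 2.

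**Figure D3:**
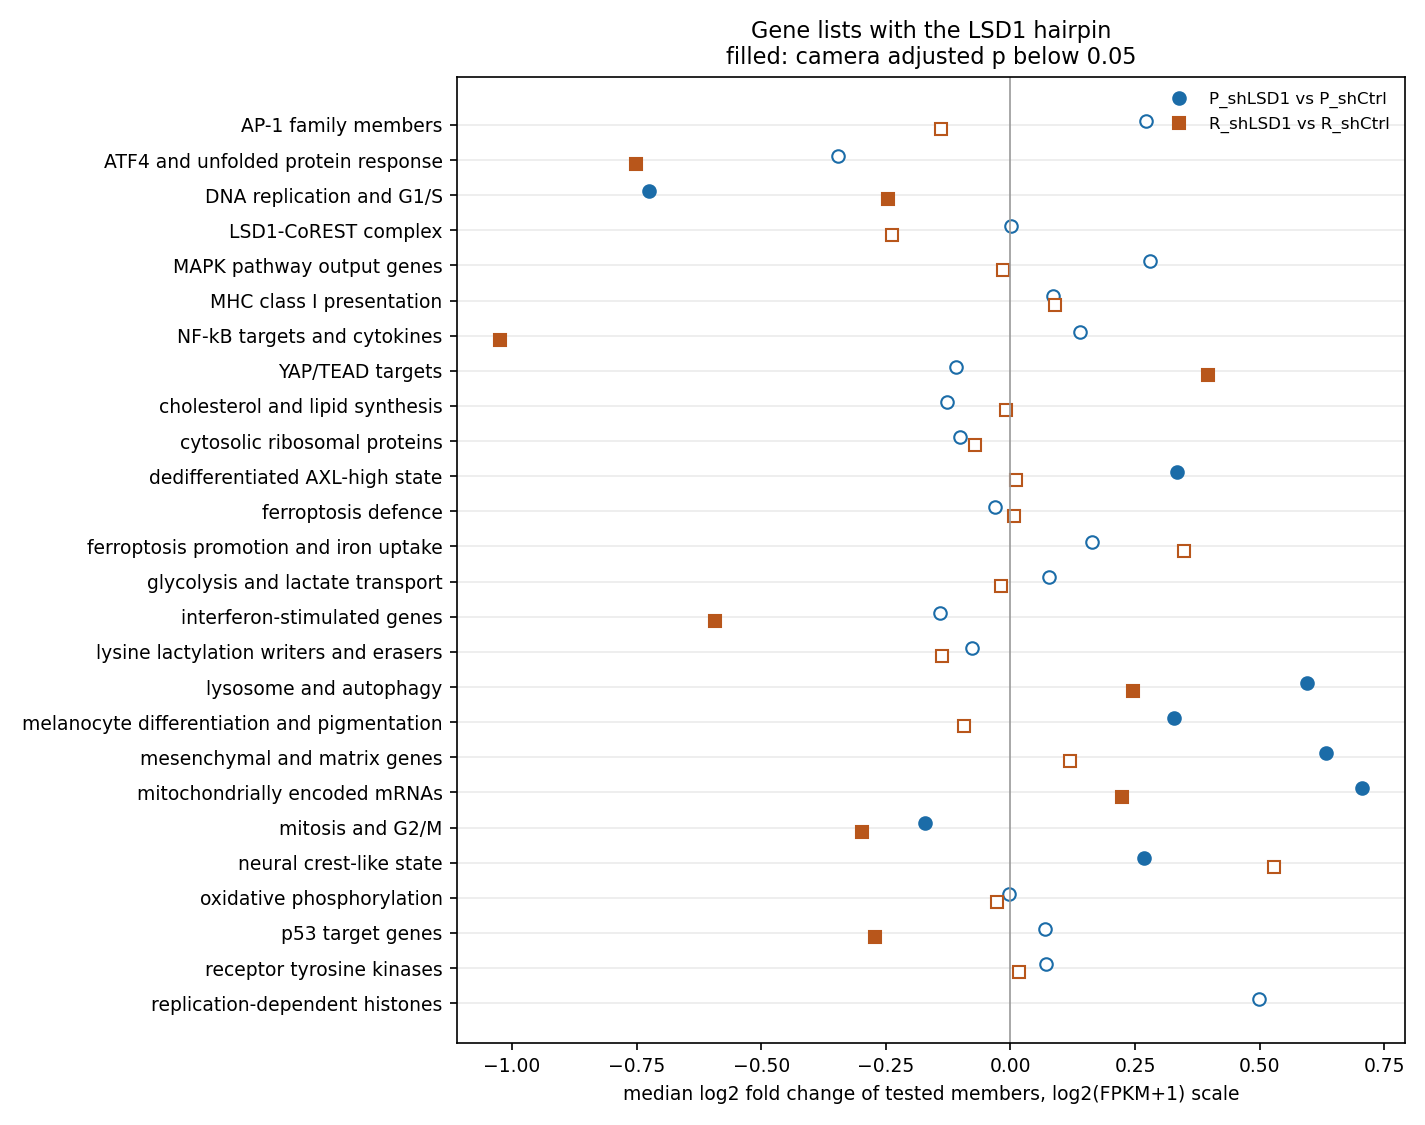
Median log2 fold change of each gene list (x axis, log2(FPKM+1) scale) for the LSD1 hairpin in P (circles) and in R (squares), filled where camera's adjusted p is below 0.05. NF-kB targets and cytokines lie at -1.02 in R and at 0.14 in P, and DNA replication genes lie below 0 in both.

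The R_shFosL1 libraries come from a table of their own without controls, so they are set beside R_shCtrl without a test. FOSL1 stood at 36.2 and 38.3 FPKM in R_shFosL1 against 109 and 104 FPKM in R_shCtrl (difference -1.49 on the log2 scale). TFRC stood at 175 and 174 FPKM against 85.2 and 90.1 (0.98), and DUSP6 at 14 and 14 against 56.7 and 48.6 (-1.83). In the other table of the R line without an LSD1 or FOSL1 hairpin, R_DMSO, TFRC averaged 122 ± 3.42 FPKM and DUSP6 34.3 ± 1.90 FPKM, between these levels. The tables differ otherwise too, with RN7SL1 at 2.49 to 23.7 FPKM in the R hairpin libraries and 320 FPKM or more in all others. Differences were 0.06 for KDM1A, 0.70 for GPX4, -0.50 for SLC7A11, 0.15 for LDHA, -0.06 for AXL, 0.00 for EGFR and -0.61 for MITF. Against R_DMSO they were -0.46 for KDM1A, -0.084 for GPX4, 1.13 for SLC7A11, 0.45 for LDHA, -0.27 for AXL, 0.14 for EGFR and -0.62 for MITF. The largest positive differences were those of the pseudogene RPS27AP5 (3.48), LCN2 (3.22), the sulfotransferase SULT1A4 (3.18), NPPB (3.16) and MKKS (3.06), and the readthrough gene MICOS10-NBL1 was listed at 0 in R_shCtrl. The largest negative differences were those of G0S2 (-3.79), the integrin ITGA2 (-3.46), MT-ATP8 (-3.14), ESM1 (-3.10) and SPOCK1 (-2.98), and BCYRN1 was listed at 0 in R_shFosL1. Against R_DMSO the differences were 2.97 for RPS27AP5, 3.35 for LCN2, 2.78 for SULT1A4, 3.01 for NPPB, 1.47 for MKKS, -2.16 for G0S2, -1.74 for ITGA2, -2.18 for MT-ATP8, -3.06 for ESM1 and -1.33 for SPOCK1.

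Median differences below those of all or nearly all of 10000 random lists of matched level were found for AXL-high genes (-0.51, percentile 0, with NT5E at -2.26 and TGFBI at -1.07), mesenchymal genes (-0.47, percentile 0, with COL6A3 at -2.38) and ATF4 genes (-0.34, percentile 0, with PSAT1 at -1.25). Against R_DMSO in place of R_shCtrl the medians were -0.0094 for AXL-high genes (NT5E -1.75, TGFBI -0.083), -0.36 for mesenchymal genes (COL6A3 -0.76) and 0.33, of the opposite sign, for ATF4 genes (PSAT1 -0.37). Cholesterol synthesis (-0.21, percentile 0.36, with INSIG1 at -1.28), lysosome (-0.16, percentile 0.72) and mitochondrially encoded mRNAs (-0.26, percentile 0.10, but 0.20 with quantile normalization) were also low (-0.91, with INSIG1 at -3.15, -0.15 and -0.18 against R_DMSO). Mitochondrial mRNAs made up 7.95% and 8.02% of R_shFosL1 against 12.8% and 13.7% of R_shCtrl. Lower by at least 1 were 3 of 13, MT-ATP8 (2129 against 18809 FPKM), MT-ND4L (3658 against 17252) and MT-ND3 (2684 against 8060). MAPK output genes lay at percentile 10.4 (median -0.10, with PHLDA1 at -1.52 and SPRY1 at 1.5), YAP/TEAD targets at 92.6 (0.18, with ANKRD1 at 1.79), ferroptosis defence at 94.1 (0.20, with GCLM at -1.21), ferroptosis promotion at 13.5 (-0.08) and NF-kB targets at 66.4 (0.09, with CCL2 at 1.32 and IL1A at -1.33). The other lists lay between percentile 12.1 (neural crest-like genes) and 86.3 (replication), with AP-1 at 76.5 and lactylation at 84.7.

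Of 14226 genes, 365 were higher and 469 lower by at least 1 with the libraries of the groups apart, 834 in all, an order that chance gives to 33.3% of genes whatever the size of the difference. By the same rule R_DMSO differed from R_shCtrl at 785 genes, and the R_shFosL1 count was 1368 with a pseudocount of 0.1. Of genes called with the LSD1 hairpin in R, 77 were also higher and 161 also lower in R_shFosL1, 238 in all against 84.7 by chance, and 35 went opposite ways. NPPB (3.06 and 3.16), the cytokine IL18 (2.52 and 2.31), ANKRD1 (2.65 and 1.79), FAM47E-STBD1 (1.71 and 1.64), the vesicle protein VAMP3 (1.79 and 1.62) and the GTPase RHEB (1.46 and 1.81) were higher in both. G0S2 (-3.63 and -3.79), HSD11B1 (-2.29 and -2.62), COL6A3 (-2.24 and -2.38), MYEOV (-2.36 and -2.03) and the ubiquitin ligase FBXO32 (-1.92 and -2.27) were lower in both, and MT1B was listed at 0 with both hairpins. Both comparisons share the 2 R_shCtrl libraries, not split here, so part of the excess may be theirs. Groups sharing controls, simulated with no gene changed, gave a mean correlation across genes of 0.50 and a covariance of 0.033, against 0.37 and 0.11 here. R_DMSO against R_shCtrl, without a FOSL1 hairpin, gave 0.29 and 0.081 with the LSD1 hairpin in R. The count fell with any R_shCtrl or R_shLSD1 library left out, and was 146 with every gene above 0 FPKM.

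Markers of other cell types were sparse. In P_DT against P_DMSO 2 of 3 measured fibroblast markers and 3 of 4 melanocytic markers rose (medians 1.08 and 1.48), 1 of 2 endothelial markers fell (-0.65), and none of 3 keratinocyte markers (-0.03) and 1 leukocyte marker (-0.53) passed limma or an unadjusted p under 0.05. In R_DT against R_DMSO 1 endothelial and 1 fibroblast marker rose (medians 1.38 and 0.75), 1 keratinocyte marker fell (-0.63), and leukocyte (-0.30) and melanocytic markers (0.30) did not pass. In R_DMSO against P_DMSO 2 of 3 fibroblast, 1 of 3 keratinocyte and 1 of 1 leukocyte markers were higher (medians 1.78, 0.32 and 1.31), 1 endothelial marker was lower (-0.66) and melanocytic markers were split 1 to 1 of 4 (-0.25). In R_DT against P_DT the medians were 1.37 for endothelial, 1.71 for fibroblast, -0.29 for keratinocyte, 1.54 for leukocyte and -1.80 for melanocytic markers. With the LSD1 hairpin 2 of 4 fibroblast markers rose in P (median 1.52) and 1 of 2 in R (0.67). The interaction term of the fibroblast set, which holds matrix genes, passed limma in 0 of 5, with 3 at an unadjusted p under 0.05 and 3 adjusted over the list alone. The fibroblast median was -1.26 (adjusted p = 0.017, 0.20 at estimated correlation). The keratinocyte, leukocyte and melanocytic medians were 0.40, 0.94 and 0.57 in P and 0.09, -0.49 and 0.23 in R. In R_shFosL1 against R_shCtrl the medians were 0.25 for fibroblast, -0.06 for keratinocyte, -0.68 for leukocyte and -0.04 for melanocytic markers, and no erythroid marker reached the level for a test in any comparison.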

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

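The LSD1 hairpin interaction, the fits with GC content and length trends removed, the crossed replicate block and the tests of the KDM1A interaction, of the spread of fold changes and of RNAs without a poly(A) tail were chosen after results were seen.

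A difference between the lines in the response to dabrafenib plus trametinib passed the interaction test at 2385 genes, among them TFRC (-0.92), SLC7A11 (2.01), DUSP6 (1.15), AXL (1.08) and EGFR (1.71). Camera called the interaction, R minus P, for ATF4 genes (median 1.18), ribosomal proteins (1.13), AXL-high genes (1.1), MAPK output genes (1.62), mitosis (-0.46), neural crest-like genes (-1.32), NF-kB targets (1.15), p53 targets (1.03), receptor tyrosine kinases (0.43), histones (-2.2) and YAP/TEAD targets (0.8). With an estimated correlation none of the 11 keeps its call. A difference in the response to the LSD1 hairpin passed at 303 genes, among them DUSP6 (-1.76). Camera called it for ATF4 (-0.42), fibroblast (-1.26), replication (0.49), interferon (-0.4), lysosome (-0.42), mesenchymal (-0.45), NF-kB (-1.19), p53 (-0.5) and YAP/TEAD lists (0.48). None keeps its call with an estimated correlation.

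The LSD1 hairpin called 504 genes in P and 3118 in R. Trends of GC content and length between the P libraries are argued against as the whole cause, since with them removed P had 1347 calls and R 3223, still 2.39 times as many. A weaker knockdown in P is argued against by the KDM1A interaction of 0.37 (SE 0.23), on the side of more loss in P, and smaller effects in P by a ratio of 0.967 between the SDs of fold changes in R and P. A wider spread in P (median SE 0.23 against 0.167 in R) stays open as a cause. The crossed replicate block (3446 calls) removes a correlation seen in the P libraries, so it cannot decide. An untested biological or table difference between the lines stays open too.

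KDM1A was higher in R_DMSO than in P_DMSO (0.94), while the control-hairpin libraries stood at 74.9 FPKM in R and 75.2 FPKM in P. Trends of GC content and length between the drug libraries are argued against, since the fold was 0.87 (SE 0.099) with them removed. A scale shared by all genes is argued against by a median of 0.125 over 9517 genes for the same difference between tables, against 0.94 for KDM1A. A difference between tables at single genes stays open, since 86.4% of genes lay below KDM1A and not all, and an effect of the control hairpin or of vehicle was not tested.

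Histone mRNAs, which mostly lack a poly(A) tail, were higher in P_DT than in P_DMSO (median 2.03). GC and length trends are argued against, since the median was 1.91 with them removed. More RNA without a tail in the P_DT libraries stays open. Of RN7SK, RN7SL1 and RN7SL2, 0 were higher in both P_DT than in both P_DMSO libraries, but for RN7SL1 and RN7SL2 P_DT lay between P_DMSO replicate 1 (485 and 92.4 FPKM) and replicate 2 (3227 and 8392 FPKM), and RN7SK alone was lower. A biological change of histone mRNA under the drugs in P stays open as well.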

How the results depend on the processing

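The fits with GC and length trends removed or a crossed replicate block and the LSD1 hairpin interaction were chosen after results were seen. So were other settings for list tests, opposite genes and shared genes, except estimated correlation, fry and folds of at least 1. Fits of the libraries of 2 groups alone equal the main fits for the hairpin tables. Leaving out a library leaves 1 sample in its group, where limma pools the spread and the lone sample is assumed to vary like the other groups. The cause of the changes below was not tested.

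With the libraries of 2 groups alone the counts were 1447 for P_DT against P_DMSO (main 3861), 2506 for R_DT against R_DMSO (main 1114), 2529 for R_DMSO against P_DMSO (main 4751) and 1041 for genes opposite between the drug response of P and the line difference (main 2321, and 1259 for folds of at least 1). With GC and length trends removed they were 2071 for R_DT, 1347 for P_shLSD1 (main 504) and 595 for the LSD1 interaction (main 303). The replicate block gave 625 for R_DT, where replicate numbers do not pair the libraries (correlations of replicate differences between groups from -0.387 to 0.134), and the crossed block 3446 for P_shLSD1 (correlation -0.548). Quantile normalization gave 879 for P_shLSD1. With every gene above 0 FPKM limma called 0 genes for P_shLSD1 (3969 at an unadjusted p under 0.05), 1609 for R_shLSD1 (main 3118), 84 for the LSD1 interaction and 146 for genes shared by R_shLSD1 and R_shFosL1 (main 238). A pseudocount of 0.1 gave 1368 for R_shFosL1 (main 834). With an estimated correlation 12 list tests passed (main 89), and fry gave 107.

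Leaving out 1 library gave 1179 to 6055 genes for P_DT, 53 to 100 for R_DT, 2266 to 5754 for R_DMSO against P_DMSO, 3551 to 3668 for R_DT against P_DT, 646 to 4521 for the drug interaction, 271 to 950 for P_shLSD1, 966 to 1439 for R_shLSD1 and 31 to 135 for the LSD1 interaction. It gave 696 to 2715 for the opposite genes and 109 to 237 for the shared genes. Signs turned for FOSL1 in R_DMSO against P_DMSO without P_DMSO replicate 2 (0.47) against -0.98 without replicate 1, RPLP0 in the drug interaction with quantile normalization (-0.0053) and ribosomal proteins in the LSD1 interaction without P_shCtrl replicate 2 (median 0.22, and -0.27 without replicate 1). Of the values of 697 single results under the alternatives 6135 gave the main call, 871 lost it, 24 gained 1 and 23 turned sign without a call. Of the list values 1886 gave the main call, 55 lost it, 47 gained 1 and 124 turned sign without a call.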

Other observations

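Every comparison in this part was chosen after the tables were seen.

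FN1, the matrix protein fibronectin, failed in the drug table and is in none of its tests. It had 195 and 197 FPKM in R_DMSO, 2732 and 2770 in R_DT, 31.2 and 27.1 in P_DMSO and 34.9 and 34.5 in P_DT.

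Genes called the same way in P_DT against P_DMSO and in P_shLSD1 against P_shCtrl numbered 166 against 59.3 by chance (72 opposite against 56.6), and in R_DT against R_DMSO and in R_shLSD1 against R_shCtrl 221 against 99.9 (100 opposite against 100.4).

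By the rule used for R_shFosL1, P_DMSO differed from P_shCtrl at 2704 of 14932 genes, and folds of R_shLSD1 correlated across genes, which are not independent replicates, at 0.37 with R_shFosL1 against R_shCtrl and at 0.087 with R_shFosL1 against R_DMSO.

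In the authors' deposited table with a p-value column, 153 genes had a deposited p-value under 0.05, and over 9962 genes its negative logarithm correlated by rank at 0.928 with the difference between the control libraries and at 0.0331 with that between hairpin and control.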
